A study of Mus musculus with 6 samples.

How the data were processed

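The series holds 6 chromatin immunoprecipitation sequencing libraries from mouse gastric corpus epithelium, released with EDTA, fixed and frozen without culture. H3K27ac, a histone mark of active promoters and enhancers, was profiled in 1 library from normal stomach and 1 from a YAP-activated tumor. YAP, the transcriptional coactivator restrained by the Hippo kinases, was profiled in 2 libraries labelled normal and 2 labelled tumor. Normal mice were wild type, and tumor mice carried a tamoxifen-inducible Cre at Clu, a tetracycline transactivator and an inducible HA-tagged Yap. Per the labels' protocols, mice received 2 mg tamoxifen on 5 days and then doxycycline food for 14 days, and libraries were read as 50 bp pairs. Nothing in the labels says that libraries of a group came from separate animals, so p-values between libraries measure only the spread between these samples, which may be technical.

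Each library was represented by 1 deposited list of peak summits, each 1 bp wide. The submitters' processing notes name Bowtie2, MACS2 and the mouse build GRCm38 (mm10). Versions, thresholds and the use of a control library are not given in the sources used here. The lists were called per sample, since every list has its own summits and peak names. The deposited score of a summit is the authors' own −log10 of a p-value or q-value (which of them is not given), and it was used only to rank or filter summits within 1 list. Depth cannot be read from summit lists and is unknown. It affects how many summits a caller returns, so lists were also compared at equal length, by keeping the best-scored summits of the longer list. Wilson 95% intervals given with shares cover counting error only.

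The words inside the peak names disagree with the labels of 2 YAP libraries. The library labelled normal 2 has peak names with the word of the tumor H3K27ac library, and the library labelled tumor 1 has names with the word cre, which the normal H3K27ac and YAP normal 1 libraries also carry. Groups were taken from the labels throughout, each YAP library is called by its label, and regrouping by the name words was run as an alternative. Yap1 itself could not settle the question, because the check planned at its exons needs exon coordinates, which were not used here. No summit of 1 YAP replicate had the same position and score as a summit of the other.

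Summits on chromosomes 1 to 19, X and Y were kept. Positions were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. YAP summits of a pair of libraries were called shared within 200 bp, and H3K27ac summits within 1 kb. The main shares between lists are given beside the share found after one list was shifted by 10 kb. A YAP site of both replicates is a summit of replicate 1 matched one to one to the nearest summit of replicate 2 and placed at the midpoint. Gene positions came from a RefSeq table of the same build with 21887 protein-coding genes. It gives the start and end of each gene but no strand, transcript start or exon. The nearest transcript start of the planned analysis was therefore replaced by the nearest end of a protein-coding gene (its start or end coordinate) within 50 kb, and the promoter share by the share of summits within 1 kb of a gene end. Exon and intron shares and the planned motif counts at YAP and H3K27ac sites were not analysed here, as no genome sequence was used.

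Before the data were examined, 19 gene lists were fixed (YAP targets, Hippo pathway, gastric cell types, transcription factor families, proliferation, matrix, cells of other kinds and comparison lists), with the tests, the alternatives and the rule for named genes. The number of list genes with a YAP site of both replicates was tested with an exact two-sided hypergeometric test within 10 strata of the length assigned to each gene, with Benjamini-Hochberg adjustment over the 19 lists. P-values were written with a floor of 1e-300. These tests set lists of genes against other genes in the same libraries. With 1 H3K27ac library per group no test was made. The log2 ratio of summits per gene (tumor + 1 over normal + 1) at equal list length was summarised by its median per list. The median's percentile among 10000 random lists of the same size, matched on strata of total summits, describes these 2 libraries. Lists in the outer 2.5 percentiles at either end are called low or high. These bounds, the mean ratio per list and the share of retained summits were not part of that plan. Groups of 2 YAP libraries were compared by an exact permutation test, whose smallest two-sided p is 0.333.

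Genes could be named from the YAP/TAZ target list without limit, up to 4 members of every other list by the rank of their best tumor YAP site or by the size of their H3K27ac difference, the 10 genes outside the lists with the best-ranked site of both tumor or both normal YAP libraries, the 10 genes with the largest excess and the 10 with the largest deficit of H3K27ac summits in tumor, and Yap1, Wwtr1, Tead1 to Tead4 and Clu. A result withheld for evaluation was left out. The overlap, list and percentile code was tested on simulated data. With 40.0% of a list planted in another, 40.4% was found. For the list test, sites were placed uniformly on the genome and reached 9024 of 21887 genes. Of 200 random lists of 20 genes without enrichment, 3.0% were called, and of 200 lists with 18 members bound, 100% were called. The real tumor YAP sites gather near gene ends and reached 13141 genes, so 3.0% is not the rate of false calls in these data. The planted effects were strong, so 100% does not give the power for weaker ones. Of 100 unchanged H3K27ac lists 2.0% were called low, and of 100 lists with summits lost 100% were. Alternatives covered score minimums of 5 and 10, distances, assignment windows, list length, the pseudocount, the background genes and leaving out each YAP library.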

Results

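The data describe where YAP binds and where H3K27ac is found in normal gastric corpus epithelium and in tumors driven by an inducible YAP transgene. H3K27ac summits on the main chromosomes numbered 22574 in the normal library and 66896 in the tumor library, a ratio of 2.96. YAP summits numbered 1654 and 2141 in the libraries labelled normal 1 and normal 2, and 38268 and 53904 in those labelled tumor 1 and tumor 2. Sequencing depth is unknown for all 6 libraries. The words in the peak names give normal 2 the word of the tumor H3K27ac library and tumor 1 the word of the normal H3K27ac library, so every direction between YAP groups below rests on labels that the files themselves contradict for those 2 libraries.

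At Yap1 (GRCm38 chromosome 9, 7931999 to 8004638), the gene whose product was induced, both H3K27ac libraries had a summit 464 or 466 bp inside the gene from its nearer end. The normal H3K27ac library had 2 summits inside Yap1 and the tumor library had 1. YAP summits inside Yap1 numbered 0 and 1 in the libraries labelled normal 1 and normal 2, and 2 and 4 in those labelled tumor 1 and tumor 2. Wwtr1, which encodes the YAP paralog TAZ, had 2 YAP sites of both tumor libraries and Tead1, which encodes a DNA-binding partner of YAP, had 6.

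The first comparison asked how much YAP binding was detected in tumor against normal epithelium. The libraries labelled tumor had a mean of 46086 ± 11056 YAP summits (SD, n = 2) and those labelled normal 1897.5 ± 344 (SD, n = 2), a 24.1-fold ratio of geometric means. The pairs were far apart compared with the differences inside them, which were 1.41-fold between the tumor libraries and 1.29-fold between the normal libraries. The exact two-sided permutation test gave p = 0.333, the smallest value that 2 libraries against 2 allow. Grouped by the words in the peak names, a choice made after the data were seen, the ratio was 1.35-fold (exact p = 0.667, n = 2 per group).

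**Figure D1:**
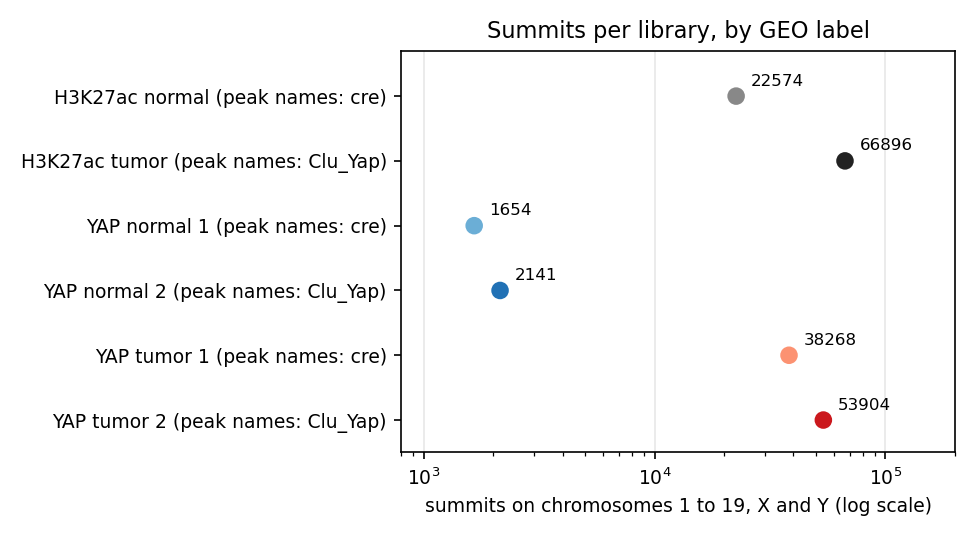
Number of summits on chromosomes 1 to 19, X and Y in each of the 6 libraries, on a log axis, with the word that each file's peak names carry. The YAP libraries labelled tumor (38268 and 53904) lie far to the right of those labelled normal (1654 and 2141), and the words split each pair.

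The libraries labelled tumor shared most of their sites. Of the 38268 summits of tumor 1, 77.1% (95% interval 76.7 to 77.5) had a tumor 2 summit within 200 bp, against 2.40% after the shift. The scores of the 29491 sites of both tumor libraries correlated across sites with a Spearman rho of 0.783, and those of the 453 sites of both normal libraries with 0.825, though sites are not independent replicates. In the libraries labelled normal, 27.4% (25.3 to 29.6) of the 1654 summits of normal 1 had a partner in normal 2, against 0.302% after the shift. The 453 sites of both normal libraries lay at 208 genes, against 13141 genes with a site of both tumor libraries. Of the 453, 311 (68.7%, 64.2 to 72.8) had a summit in both tumor libraries, against 0.442% after the shift. With the tumor lists shortened to the length of the normal lists this share was 20.8%. It was 45.3% of the summits of normal 2 alone and 21.6% of those of normal 1 alone.

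Genomic context separated the library labelled normal 1 from the other 5. Only 18 of its 1654 summits (1.09%, 0.689 to 1.71) lay within 1 kb of a gene end, below the 2.91% of the genome that lies so close to one. The share was 32.3% in normal 2, 30.3% in tumor 1 and 24.3% in tumor 2, and 51.1% and 22.9% in the normal and tumor H3K27ac libraries. The means were 27.3 ± 4.25% for tumor and 16.7 ± 22.1% for normal YAP (SD, n = 2 each), and the difference of 10.6 points was smaller than the normal spread (exact permutation p = 1.0, n = 2 per group). Without normal 1 the difference was -4.99 points, opposite in sign. At the length of the shortest list it was 53.1 points (exact permutation p = 0.333, n = 2 per group). In tumor 1 and tumor 2, the best-scored decile of summits had 70.2% and 69.5% near gene ends, while in normal 2 the best decile had 5.61%.

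**Figure D2:**
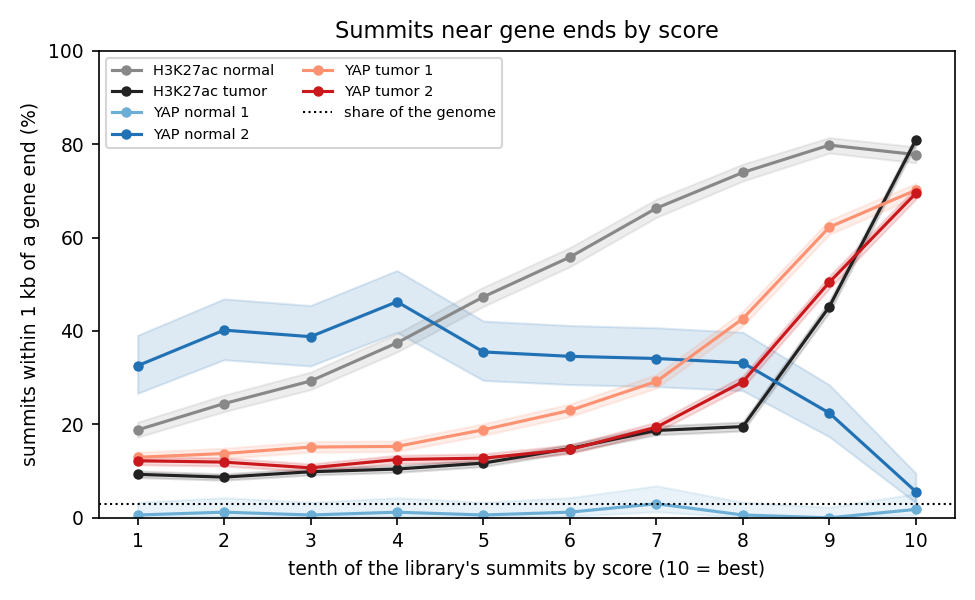
Percent of summits within 1 kb of a gene end in each decile of a library's summits ordered by its own score, with Wilson 95% bands; the dotted line is the 2.91% of the genome that lies so close. The tumor YAP and both H3K27ac lists climb towards the best scores, normal 1 stays near the genome share, and normal 2 falls to 5.61% in its best decile.

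Next, the genes bound in the libraries labelled tumor were set against gene lists. Of the 28 YAP/TAZ targets, genes used as readouts of YAP activity, 22 had a site of both tumor libraries against 18.3 expected (adjusted p = 0.233, exact test), a difference that did not pass the test. Amotl2, which encodes a YAP-binding junction protein, had 8 such sites, the best of them at chromosome 9, position 102717728, inside the gene and 637 bp from its nearer end, ranked 1000 or better in both tumor libraries. Ccn1 and Ptpn14 had 6 sites each, Myof and Wwc1 had 4 each, and F3, which encodes tissue factor, had 3. Gadd45a had 2, the best of them at chromosome 6, position 67037414, 7 bp outside the gene. Frmd6 was the 1 target with a site of both normal libraries. Ccn2, Ankrd1, Axl, Tgfb2, Fjx1 and Rbms3 had no site of both tumor libraries assigned. With tumor 2 alone 27 of the 28 were bound and the list passed (adjusted p = 0.018, exact test), while with tumor 1 alone 24 were bound (0.163), and over 9 alternatives the exact p ranged from 0.018 to 0.949.

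AP-1 genes, which encode Fos and Jun family transcription factors, all carried YAP: 14 of 14 had a site of both tumor libraries against 8.22 expected (adjusted p = 0.00383, exact test). Fos had 9 sites, with its best at chromosome 12, position 85486080, 8806 bp outside the gene, Atf3 had 4, Junb 3 and Jund 2. Proliferation genes were also bound above expectation, with 22 of 25 against 14.3 (adjusted p = 0.00738, exact test). Aurka, a mitotic kinase gene, had a site 1 bp outside its end at chromosome 2, position 172370887. Ccne1, which encodes cyclin E1, had 4 sites, and Rrm2, which encodes a ribonucleotide reductase subunit, had 6. Housekeeping genes, included as a comparison list, were also bound above expectation, 17 of 18 against 10.04 expected (adjusted p = 0.00383, exact test), with Polr2a and Ppia among them. Among the 14475 genes with an H3K27ac summit within 1 kb of an end, no list passed above expectation, and the adjusted exact p was 0.145 for AP-1, 0.319 for proliferation and 0.145 for housekeeping genes. These were the highest of 9 alternatives for the 3 lists, and the lowest were 8.5e-04, 0.00189 and 6.6e-05, so with this background all 3 calls ended, at 13 of 13, 22 of 25 and 15 of 16 genes bound. With 13 of 13 AP-1 genes bound, the list was at its ceiling there.

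Hippo pathway genes had 22 of 25 bound against 16.2 expected, just outside the threshold (adjusted p = 0.0578, exact test). Mob1a, Taok1 and Taok3, parts of the kinase cascade, had 1, 2 and 3 sites. This list passed under 7 of 9 alternatives, among them either tumor library alone and score minimums of 5 and 10, with adjusted exact p from 0.00396 to 0.71 over all 9. Of the metaplasia (SPEM) markers, 16 of 20 were bound, with Clu, Mal2 and Sox9 among them, and of the regenerative or fetal-like genes 20 of 25, with Itga6, Ereg and Plaur among them. Both had an adjusted exact p of 0.177. At a score of at least 10 only 4 of the 20 SPEM markers were bound, -19.8 points from expectation, so their direction turned. Clu, whose locus drives the Cre, had 2 sites, the best at chromosome 14, position 65968564, inside the gene 81 bp from its end. Regenerative genes passed with tumor 2 alone (25 of 25, adjusted exact p = 0.00423), but not with tumor 1 alone (0.0827). No gastric cell-type list passed with sites of both tumor libraries, with 10 of 14 chief cell genes (Xbp1 had 6 sites), 13 of 20 parietal cell genes (Ezr had 7) and 11 of 14 pit cell genes (Foxq1 had 8), at adjusted exact p of 0.475, 0.827 and 0.233. Pit cell genes passed with tumor 2 alone (14 of 14, adjusted exact p = 0.018, against 0.0516 with tumor 1 alone) and parietal cell genes with tumor 1 alone (19 of 20, 0.0171, against 0.138 with tumor 2 alone). Gastric lineage transcription factors had 17 of 20 (Elf3 6 sites, Sox21 4, adjusted exact p = 0.139) and passed with either tumor library alone (0.0133 and 0.0283) and within 100 kb (0.0452), and matrix and EMT genes 16 of 23 (Itgb6 4 sites, adjusted exact p = 0.827).

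YAP was found less often than expected at 2 of the lists of genes from other cell kinds, the immune and the olfactory and vomeronasal receptor lists. Immune genes had 5 of 20 bound against 11.8 expected (adjusted exact p = 0.00897), Spi1, Cd3e, Itgam and S100a9 among the 5. Only 5 immune genes had H3K27ac near an end, and among these the deficit was -38.2 points against -34.0 for the list, with an adjusted exact p of 0.171. Olfactory and vomeronasal receptor genes, which serve sensory neurons, had 43 of 1465 bound against 828 (adjusted exact p at the floor of 1e-300). The other lists did not pass in the main test: fibroblast, muscle and endothelial genes had 9 of 18 (adjusted exact p = 0.384), squamous genes 6 of 14 (0.35), endocrine and tuft cell genes 8 of 18 (0.233), intestinal genes 5 of 14 (0.177) and genes of neighbouring organs 3 of 12 (0.0911). At a score of at least 5 endocrine and tuft cell genes (4 of 18, adjusted exact p = 0.0168), squamous genes (1 of 14, 0.00345) and genes of neighbouring organs (1 of 12, 0.00643) passed below expectation. Endocrine and tuft cell genes and squamous genes also passed at 10 (both 0.0045), endocrine and tuft cell genes (0.0173) and genes of neighbouring organs (0.0315) among genes with H3K27ac near an end, and genes of neighbouring organs within 10 kb (0.0456), all by the adjusted exact p. With either tumor library alone none of these 3 lists passed. For the libraries labelled normal, no list passed in either direction among 208 genes with a site (adjusted p = 1.0 for all 19 lists, exact test), and 0 lists had an unadjusted p under 0.05. Outside the receptor list (7 bound against 7.38 expected), at most 0.406 genes were expected per list, that of YAP/TAZ targets. Those lists could not pass below expectation and had little room to pass above it, so their outcome says little. Normal 1 alone put the olfactory and vomeronasal receptor genes above expectation (39 genes, adjusted exact p = 0.00382), and normal 2 alone put them below (17 genes, 1.5e-11).

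**Figure D3:**
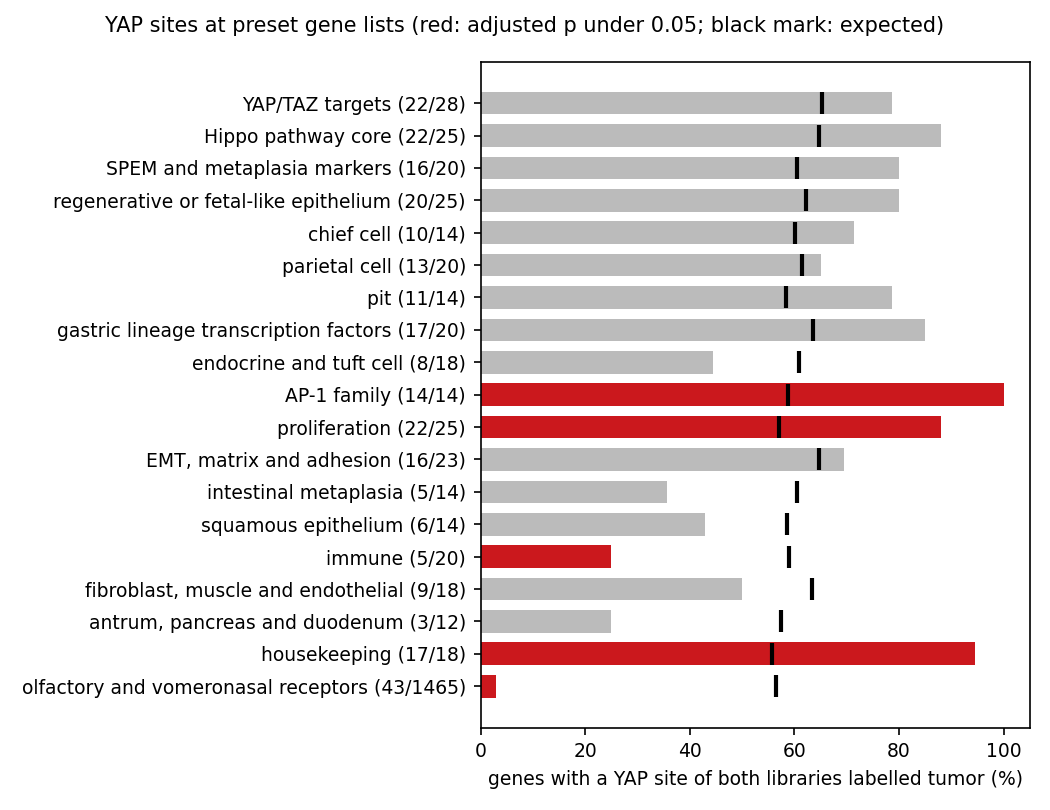
Percent of the genes of each of the 19 preset lists with a YAP site of both libraries labelled tumor; bars start at 0, red bars passed the exact test after adjustment, and black marks give the percent expected. AP-1 (14 of 14), proliferation (22 of 25) and housekeeping genes (17 of 18) exceed their marks, while immune (5 of 20) and olfactory and vomeronasal receptor genes (43 of 1465) fall short.

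The YAP sites at the very top of the ranking were shared by both labels, with 35 of the best 50 and 50 of the best 100 tumor sites found in all 4 YAP libraries. The genes outside the lists with the best site of both tumor libraries were Rpusd4, Tmem196, Mrgprd, Gm45871, Gm14496, Wls, Filip1l, Zc3h7a, Cdk8 and 4930467E23Rik, and 8 of these 10 were also among the 10 with the best site of both normal libraries, with Ly6c2 and Tcstv3 in addition. The first of them, at chromosome 9, position 35305405, 29448 bp outside Rpusd4, ranked 1 in tumor 1 and tumor 2 and lay 1 and 4 bp from a summit of normal 1 and normal 2 and 16 and 9 bp from a summit of the normal and tumor H3K27ac libraries. The sites 7591 bp outside Tmem196 and 17086 bp outside Mrgprd likewise had a summit of each of the 6 libraries within 52 bp. When sites with a normal YAP summit within 1 kb were left out, a choice made after the data were seen, the best sites lay at Col19a1, Mpp7, Polr3f and Fyco1. That of Mpp7, which encodes a polarity scaffold, lay inside the gene at chromosome 18, position 7609150, 17739 bp from its nearer end.

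The H3K27ac comparison asked which elements were active in tumor and in normal epithelium. There is 1 library per group and no replicate check. Of the normal summits, 79.8% (79.3 to 80.3) had a tumor summit within 1 kb, against 11.4% after the shift. Of the tumor summits, 24.7% (24.4 to 25.1) had a normal summit, against 3.72%. With both lists at 22574 summits these shares were 67.0% and 57.8%. The sets at that length were 9519 summits in the tumor list alone, 7442 in the normal list alone and 13055 shared. Against the full tumor list, 4556 normal summits had no tumor summit within 1 kb. The normal set thus holds summits whose tumor partner was cut with the shortened list. Of the shared summits 69.2% lay near gene ends, against 12.7% of the tumor set and 12.4% of the normal set. Receptor genes for odorants and pheromones held 224 summits of the tumor set and 15 of the normal set.

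Genes of differentiated gastric cells had fewer H3K27ac summits in the tumor library at equal list length. Pit cell genes, which make surface mucus, had 4 summits in tumor and 19 in normal, with 9 of 14 genes lower and 0 higher, a median log2 ratio of -1.0 and a percentile of 0. Gkn1, a gastrokine gene, and Muc5ac, the surface mucin gene, each had 2 normal summits and 0 tumor summits, and Foxq1, which encodes a regulator of Muc5ac, had 5 and 1. Parietal cell genes, which serve acid secretion, had 29 tumor and 59 normal summits, with 12 of 20 genes lower and 2 higher (median -0.70, percentile 0.03). Kcnj15, a potassium channel gene, had 6 normal and 0 tumor summits, Ppargc1a, a regulator of mitochondria, 4 and 0, and Slc26a7, a chloride transporter gene, 3 and 0. Chief cell genes, which serve digestive enzyme secretion, had 10 tumor and 26 normal summits, with 7 of 14 genes lower and 0 higher (median -0.29, percentile 0.59). Cblif, the gene of gastric intrinsic factor, had 5 normal and 1 tumor summits, Pgc, a pepsinogen gene, 3 and 0, and Xbp1, a secretory regulator gene, 7 and 3. In the full tumor list Muc5ac had 2 summits, Ppargc1a 4, Pgc 3 and Xbp1 8, as many as in normal or more, while Gkn1 had 0, Cblif 1, Foxq1 2, Slc26a7 2 and Kcnj15 4. That list is longer than the normal one, so equal counts show that summits were present but not that a relative deficit was gone.

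Those medians depended on list length and assignment. With the full lists the chief and parietal medians were 0.085 (percentile 3.07) and 0.32 (percentile 0.785), and that of pit cell genes was 0 (percentile 3.82). The full tumor list is longer than the normal one, which raises ratios in general, so the turn of sign alone does not end a call. Against random lists parietal cell genes stayed low, while chief and pit cell genes were no longer called. With gene ends within 10 kb only the pit list stayed under percentile 2.5. The chief median was 0 when summits inside a gene were assigned to it (percentile 50.6) and when summits closer than 2 kb were merged (percentile 50.0), which ended that call. The olfactory and vomeronasal receptor genes had 237 tumor and 27 normal summits, a mean log2 ratio of 0.14 at percentile 100. These summits take places in a tumor list of fixed length, but only 237 of its 22574.

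At equal list length the medians of the remaining lists were neither low nor high. Where most genes of a list had no summit in either library, the median had to be 0, so that outcome says nothing. This held for olfactory and vomeronasal receptor (1239 of 1465), immune (15 of 20) and squamous genes (11 of 14). It also held for endocrine and tuft cell genes (10 of 18) and genes of neighbouring organs (7 of 12). With full lists AP-1 genes (percentile 0.515) and gastric lineage transcription factors (1.58) were low, while endocrine and tuft cell genes (99.95), genes of neighbouring organs (99.2) and fibroblast, muscle and endothelial genes (97.8) were high. Below, the tumor number comes first for lists, and the normal number first for single genes. YAP/TAZ targets had 41 tumor and 54 normal summits, with 8 genes higher and 12 lower (median 0, percentile 57.5). Tead1 and Myof each had 4 and 1, but 7 and 4 tumor summits in the full list. Proliferation genes had 31 and 25 summits, 8 higher and 4 lower, with a median of 0 and a mean of 0.25 at percentile 97.1, and Ccne1 had 0 and 3. Regenerative genes had 20 and 26, with Ereg at 4 and 1. Metaplasia markers had 15 and 16, gastric lineage transcription factors 58 and 67, with Ehf at 5 and 0, and AP-1 genes 31 and 43. Hippo genes had 33 and 45, matrix and EMT genes 27 and 30, housekeeping genes 24 and 32, and fibroblast, muscle and endothelial genes 8 and 17. Outside the lists, the 10 genes with the largest deficit in tumor included Sik1 (13 and 4), Deptor (10 and 1), Pxylp1 (10 and 1), Bcas1 (9 and 0) and Mbnl2 (9 and 1). The others were Gm20914 on chromosome Y (9 and 0), Gm17019 (12 and 1), Gm10354 and Speer4c (10 and 1 each) and Speer4d (9 and 0). The last 4 lie between positions 14974144 and 15714298 of chromosome 5. The largest excess was at Zswim2 (0 and 7), Foxp4 (4 and 9), Ahdc1 (7 and 12) and Tnrc18 (4 and 8). Next came 4921507P07Rik and Ccl21b (1 and 5 each), Zfp991, Gm8765 and Zc3h12b (0 and 4 each) and Tmx3 (1 and 4). In the full tumor list Sik1 had 15 and Pxylp1 12, more than in normal, Bcas1 6 and Deptor 4.

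**Figure D4:**
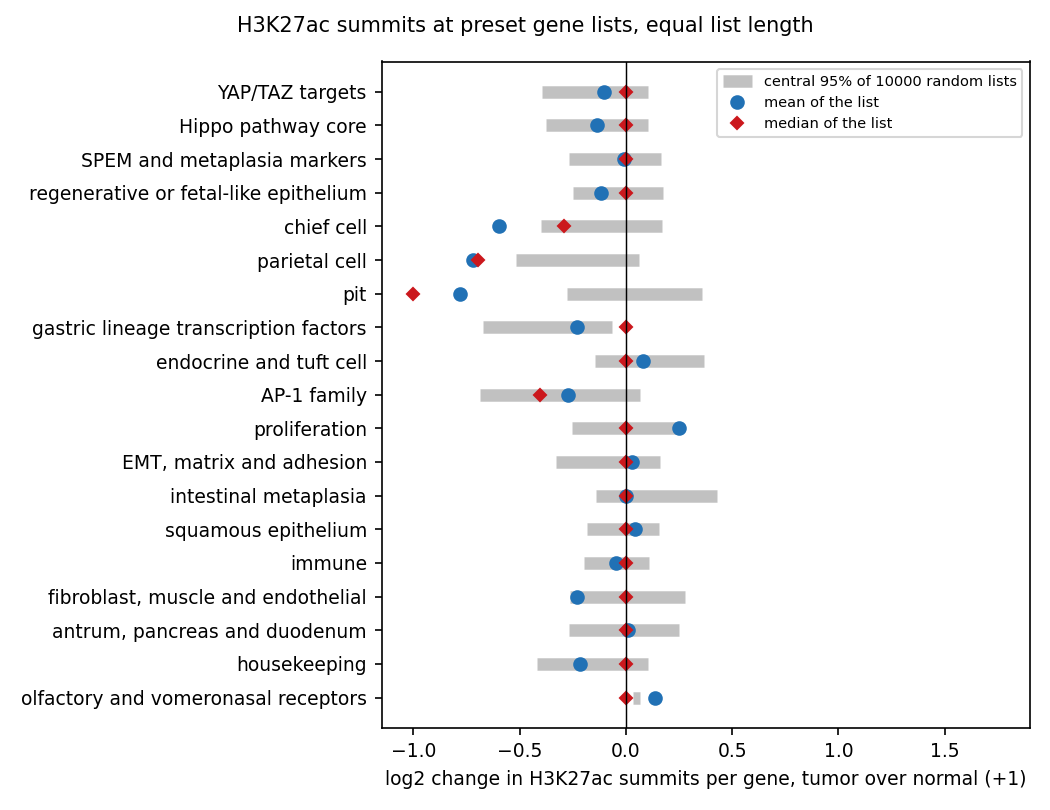
Mean (blue) and median (red) log2 ratio of H3K27ac summits per gene, tumor over normal with 1 added to each, for the 19 lists at equal list length; grey bars hold the means of the central 95% of 10000 random lists. Pit (median -1.0), parietal (-0.70) and chief cell genes (-0.29) have the lowest means, left of their bars.

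YAP and H3K27ac were then set side by side. Of the YAP summits of tumor 1 and tumor 2, 50.8% and 42.0% lay within 1 kb of a tumor H3K27ac summit and 44.5% and 34.8% within 1 kb of a normal one, against means of 10.4% and 4.46% after the shift. For normal 1 and normal 2 the shares were 58.5% and 88.8% for tumor H3K27ac and 26.0% and 61.8% for normal H3K27ac, against means of 6.17% and 3.26% after the shift. At equal H3K27ac length, tumor YAP summits lay more often at normal-only than at tumor-only H3K27ac: 4470 against 2002 for tumor 1 and 5535 against 2268 for tumor 2. The normal YAP libraries had 200 against 499 for normal 1 and 264 against 595 for normal 2. With full H3K27ac lists the tumor YAP direction turned, to 2555 against 4977 for tumor 1 and 3260 against 7130 for tumor 2, while normal 1 had 66 against 604 and normal 2 had 103 against 680. At equal length both tumor YAP libraries had a summit near 90.6% of shared H3K27ac summits, 60.5% (59.4 to 61.6) of the normal set and 14.2% (13.5 to 14.9) of the tumor set. Tumor 1 alone was near 64.3% of the normal set, against 9.55% after the shift, and near 20.2% of the tumor set, against 3.11%. For tumor 2 these shares were 75.5% against 13.3% and 22.0% against 4.60%. Places 10 kb from the tumor set thus also held fewer YAP summits, so part of the gap between the sets lies in their surroundings.

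Counted by gene, 3599 genes had more H3K27ac summits in the tumor library, 4493 had fewer and 6295 had the same number above 0. A YAP site of both tumor libraries was assigned to 54.3% (52.7 to 55.9), 87.6% (86.6 to 88.5) and 87.6% (86.7 to 88.4) of them. Within strata of total summits the difference between genes with more and genes with fewer was -15.9 points (-17.8 to -14.1), and it kept its sign under the 6 alternatives run for it, from -20.8 to -9.32. The interval of this difference counts genes as independent and covers no spread between libraries. Bcas1 and Deptor, with far fewer H3K27ac summits in tumor, had 10 and 9 tumor YAP sites, and Sik1 and Pxylp1 had 6 each. Among genes with more, Zswim2 had 0, Foxp4 7, Ahdc1 5 and Tnrc18 4.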

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

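The values here were chosen after the lists had been seen, and no explanation was tested for them. Summits on the mitochondrial genome, which no comparison used, numbered 12 in the YAP library labelled tumor 1 and 13 in that labelled tumor 2, above the 1 and 0 of the libraries labelled normal 1 and normal 2. The excess is in counts and not in shares, since these were 12 of 38356, 13 of 54010, 1 of 1685 and 0 of 2184 deposited summits. Both H3K27ac libraries had 0.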

How the results depend on the processing

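Chosen after seeing the data were regrouping by peak-name words, assignment by gene body, leaving out summits within 1 kb of normal 1, merging H3K27ac summits closer than 2 kb and merging them in full lists; the other alternatives were planned. The motif results, exon shares and the variants that needed transcript starts or genome sequence were not run. Causes of the changes were not tested, except where a stricter distance or a shorter list lowers a share by construction. The ratio of YAP summit numbers (log2 4.59) ranged from 0.43, by peak-name words, to 5.51 at a score of at least 10, that is 45.6-fold, and from 4.35 to 4.84 when 1 library was left out. Pairing the libraries by replicate number, which labels do not tie to a shared animal or day, left the log2 ratio at 4.59 (exact sign-flip p = 0.5, the smallest for 2 pairs) and the gene-end difference at 10.6 points. That replicate block changed no call, and 2 pairs are too few to check whether the numbers pair the samples. The gene-end difference ranged from -4.99 (without normal 1, reversed) to 26.2 points when 1 library was left out. Replicate agreement (tumor 77.1%, normal 27.4%) was 59.5% and 23.3% at 100 bp, 85.9% and 31.4% at 500 bp, 83.7% and 38.3% at a score of at least 5 and 88.0% and 67.9% at 10, and for tumor 68.7% at equal length. Normal sites found in tumor (68.7%) were 74.1% at a score of at least 5, 20.8% with tumor lists shortened to normal length, and 21.6% to 75.3% when 1 library was left out. Normal H3K27ac summits with a tumor summit (79.8%) and tumor summits with a normal one (24.7%) were 69.4% and 22.8% at 500 bp, 82.9% and 26.3% at 2 kb, 67.0% and 57.8% at equal length, 83.0% and 23.6% at a score of at least 5 and 89.8% and 27.4% at 10. Tumor YAP near tumor H3K27ac (46.4%) was 40.02% at 500 bp and 33.4% at equal H3K27ac length, tumor YAP near normal H3K27ac (39.7%) was 47.9% at a score of at least 5, and normal YAP near tumor H3K27ac (73.7%) was 44.5% without summits within 1 kb of normal 1, which removes the partners of normal 1 by construction. Lists bound above expectation by tumor YAP (3) numbered 5 within 100 kb, 0 among genes with H3K27ac near an end, and 6 to 8 when 1 tumor library was left out; lists below (2) numbered 5 at a score of at least 5 and 4 at 10. For normal YAP the counts above and below (0 and 0) each ranged from 0 to 1 when 1 library was left out. Lists with high H3K27ac ratios (0) numbered 3 with full lists and 2 with full merged lists, and lists with low ratios (3) numbered 1 within 10 kb, 2 by gene body and 2 with merged summits, the chief list being lost in all 3 settings. The chief and parietal medians reversed with full lists (0.085 and 0.32) and with full merged lists (0.32 and 0.50). The difference in YAP share between genes with more and fewer H3K27ac summits (-15.9 points) was -18.8 with full lists, -9.32 within 10 kb, -20.8 with merged summits and -14.6 to -13.9 when 1 tumor YAP library was left out. Single lists bound by tumor YAP that reversed, in points from expectation, were parietal (-5.48) and EMT (-8.68) within 10 kb, EMT (-1.37) at a score of at least 5, SPEM (-19.8), chief (-11.3), parietal (-0.198), pit (-2.43) and EMT (-7.53) at 10, and parietal (-5.88) and EMT (-20.3) among genes with H3K27ac near an end; fibroblast, muscle and endothelial genes ranged from -3.04 to 4.17 when 1 tumor library was left out. For normal YAP, YAP/TAZ targets and Hippo genes reversed within 10 kb (-0.419 and -0.408) and at a score of at least 10 (-0.746 and -0.778), and olfactory and vomeronasal receptor genes within 100 kb (0.102) and at 10 (0.0962). Leaving out 1 normal library gave YAP/TAZ targets -1.04 to -0.798, regenerative 0.829 to 1.36, chief -2.57 to 8.45, pit -2.78 to 1.29, gastric factors -4.65 to 6.70, endocrine and tuft -5.83 to 8.55, intestinal -5.70 to 4.72, squamous -2.25 to 1.70, housekeeping -1.43 to 12.6 and olfactory and vomeronasal receptor genes -3.16 to 1.22. In all, among single gene lists 381 comparisons with an alternative kept their side of the threshold without turning sign in a tested list, 23 passed newly, 4 no longer passed, 15 untested values moved and 33 reversed. A score of at least 10 left 11575 of 29491 tumor sites (8663 of 13141 genes) and 214 of 453 normal sites, and leaving out 1 library gave 53904 or 38268 tumor sites and 2141 or 1654 normal sites. Unknown depth limits every comparison of summit numbers.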

Other observations

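The tests of the label exchange, of the library numbers and of the sites found in all YAP libraries were chosen after those results had been seen, as was the measure of retained summits; what the tests of merging and of score ranking should show was written before their results were seen. Retained summits, the share of normal H3K27ac summits with a tumor summit within 1 kb in the full lists, was set against normal summits of the same score without adjustment over the 19 lists, and its intervals cover counting error only. Proliferation genes kept 24 of 25 (96.0%, 80.5 to 99.3) against 77.4% for normal summits of the same score. Matrix and EMT genes kept 27 of 30 (95% interval 74.4 to 96.5%) against 73.9%. AP-1 genes kept 39 of 43 (90.7%, 78.4 to 96.3) against 83.5%, an interval that holds the reference share. Endocrine and tuft cell genes had 5 normal summits, of which 1 was retained, while Chga, Dclk1 and Slc18a2 each had 0 normal summits and 1 tumor summit at equal length.

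Summits found in the tumor H3K27ac library alone were unlike the shared ones. In the full list, 50346 of 66896 tumor summits had no normal summit within 1 kb, and 10.9% of these lay near a gene end and 8.06% (7.82 to 8.30) near YAP of both tumor libraries. The best-scored decile of the tumor list had 80.9% near gene ends and 99.8% near normal H3K27ac, while its second-lowest decile had 8.71% and 5.58%. Zswim2, with the largest excess among genes outside the lists, had 0 normal summits and 7 tumor summits and no YAP site of both tumor libraries.

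Fewer H3K27ac summits at pit, parietal and chief cell genes in the tumor library may come from broader tumor peaks that merge several summits, or from tumor summits elsewhere that displaced these by score. After summits closer than 2 kb were merged in both libraries, the median stayed at percentile 0.015 for pit and 0.005 for parietal cell genes, against merging, while for chief cell genes it moved to 50.0 (median 0), as merging predicts. That chief result does not single out merging. Before it, 7 of 14 chief cell genes were lower and 0 higher, so a change at 1 of the 7 could bring the median to 0. The chief mean before merging was -0.60 (percentile 0.04). In the full tumor list pit cell genes retained 47.4% of normal summits (27.3 to 68.3), below the 72.7% for the same score, which argues against displacement. Parietal cell genes retained 66.1% (53.4 to 76.9) against 73.5% and chief cell genes 84.6% (66.5 to 93.9) against 76.5%. Displacement predicts a share equal to the reference, and both intervals hold it, so displacement stays open for these lists. For pit cell genes the median was 0 with full lists (percentile 3.82) and with full merged lists (percentile 17.4), so the median does not show their deficit apart from list length. Their retained share, measured in the full tumor list, was below its reference. Depth, cell makeup and chance between single libraries stay open.

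The excess of YAP summits in the libraries labelled tumor may reflect the transgene, but the peak names allow an exchange of normal 2 and tumor 1. If tumor 1 were a normal library, tumor 2 could carry relatively more summits at target, metaplasia and regenerative genes than at chief, parietal and pit cell genes. At equal length, tumor 2 had 207 and 126 and tumor 1 had 175 and 124, an odds ratio of 1.16 (0.835 to 1.62, Fisher's exact p = 0.371), which does not decide between the labels and the names. Summits were counted as independent, although tumor 1 and tumor 2 share most sites and a gene can hold several. The interval and the p-value of that Fisher's test therefore do not measure spread between libraries. Library numbers 1 and 2 belong to the label normal and 7 and 12 to the label tumor, so a batch and the labels cannot be told apart, with a 24.1-fold ratio between the number pairs and 1.29-fold and 1.41-fold within them. The labels do not say that these numbers mark batches. By the words in the peak names, each number pair holds 1 library of each word. Under the names, the 24.1-fold ratio would thus lie between number pairs, and 1.29-fold and 1.41-fold would be the ratios between the words.

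Some YAP sites recurred in all YAP lists: 316 tumor sites were within 200 bp of a summit of both normal libraries, including 50 of the best 100 tumor sites, though their median worse rank was 8098. Of the 316, 78.2% lay near H3K27ac summits of both libraries, but 3.16% (1.73 to 5.73) lay within 1 kb of a gene end, close to the 2.91% of the genome. Other tumor sites near H3K27ac of both libraries had 66.9%, but the sites had to match normal 1, whose summits allow at most 7.28%, so the difference was fixed by that selection. Regions that collect reads with any antibody and YAP binding at elements active in both tissues both stay open for the sites near Rpusd4, Tmem196 and Mrgprd. A list of regions of the first kind was not used here.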
